A study of Mus musculus with 4 samples.

How the data were processed

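Polyadenylated RNA was sequenced from 4 cultures of MMTV-Myc cells, with 1 library in each of 4 groups. These are mouse mammary tumour cells driven by a Myc transgene under the mouse mammary tumour virus promoter. The groups were bulk cells (day 0), mammosphere cells (day 20), cells carrying a control short hairpin RNA (shRNA) and cells carrying an shRNA against Cbx8. Per the labels' protocols, bulk cells grew in medium with serum and insulin, whereas mammospheres (MS) grew without attachment in medium with EGF, bFGF and a supplement. Hairpins were delivered by lentivirus and cells were selected and passaged in puromycin. Whether the shRNA cultures grew attached or as spheres is not given in the sources used here. The control hairpin is described in one label as scrambled and in another, and in the table header, as directed against luciferase.

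Per the submitters' processing notes, the tools were FastQC 0.10.0, TopHat 1.4.0, Cufflinks 1.3.0 and Cuffdiff, whose version is listed as 0.0.7, with genome build mm9. The notes name these tools without their settings. The authors deposited 2 Cuffdiff tables, one for each pair of libraries, with FPKM (fragments scaled to transcript length and library size) per gene. The same deposited tables hold the authors' log2 ratio, test statistic, p-value and q-value for each row. How the authors assigned reads that map to several places is not given in the sources used here. Depth is unknown: the files hold no counts, and low FPKM values showed no whole-read steps, so no counting interval or detection floor was computed.

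The bulk and mammosphere table had 22440 rows, of which 4045 were tested by the authors (status OK), 18363 were not tested, 29 failed and 3 held too many fragments to be estimated. No untested row exceeded 25.2 FPKM in the bulk library or 18.5 FPKM in the mammosphere library, so the tested rows are the abundant ones. The knockdown table had 11708 rows, all with status OK. None of its rows was at 0 in either library, whereas 5458 rows were at 0 in the bulk and 7229 in the mammosphere library. Genes silent in a library may therefore be missing from the knockdown table. In 15 of them a value was exactly 1 and no statistic was given. The tables came from separate runs and share no library, so every fold change in the report was computed within a table. Where the closing section sets levels from both tables side by side, it says so.

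Fold changes were computed here as log2((FPKM + 1)/(FPKM + 1)), a scale that understates the change of low genes, with the mammosphere over the bulk library and the knockdown over the control library. Genes were counted as higher or lower at 2-fold or more, among rows with status OK and an FPKM of at least 1 in either library. Counts of gene list members also took in rows that the authors did not test. With 1 library per group no test across replicates exists, and no p-value was computed. The authors' q is quoted only as the value in the authors' deposited table.

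A set of 34 gene lists covering pathways, complexes and cell type markers was fixed before the data were examined. For each list with 3 or more members at 1 FPKM or above in either library, the median log2 fold change was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. The two-sided share was adjusted over the lists of a comparison by Benjamini-Hochberg, as a description of these libraries. A list is said to lie above or below random lists where that adjusted share was under 0.05.

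The genes named in the report follow a rule fixed at the same time: Cbx8 and Wdr5, the 10 largest increases and decreases among tested genes with 5 FPKM or more in the higher library (predicted and small RNA models left out), up to 4 members with the largest absolute change from each list, and every measured Notch pathway and PRC1 (Polycomb repressive complex) member. Other genes are marked where they appear. On simulated data, with an assumed log2 SD of 0.2 between libraries, the counting step recovered 100% of genes changed by a log2 of 2 or 1.5 and called 0% of unchanged genes, in both comparisons (4045 and 10685 genes). The list step recovered 100% of 20 lists shifted by a log2 of 0.3, and 4% of 100 unchanged lists fell outside the middle 95% in each comparison. These simulations check only that the steps run as meant. No replicate measured the SD of 0.2, which lies far inside the 2-fold limit and was the same at every level. Random lists in the mammosphere comparison were wider (−0.56 to 0.09 for 20 PRC1 genes). Recovery of a 0.3 shift therefore does not carry over to it.

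Alternatives were pseudocounts of 0.1 and 5 FPKM, other FPKM minimums, fold limits of 1.5 and 4, centring of fold changes on the median gene, equal upper quartiles, all rows whatever their status, summed rows of the same symbol, matching in 10 bins and the authors' own calls. Gene symbols and coordinates (mm9) are those of the deposited tables. Computation used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and matplotlib 3.10.9 for figures.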

Results

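Gene expression was compared in MMTV-Myc mouse mammary tumour cells in 2 settings. The first set cells kept as mammospheres, clusters grown on low attachment plates with growth factors, against bulk cells grown with serum. The second set cells with an shRNA against Cbx8, a chromodomain subunit of Polycomb repressive complex 1 (PRC1), against cells with a control shRNA. The series title names Cbx8 together with Wdr5, a core subunit of the histone H3 lysine 4 (H3K4) methyltransferase complexes, in mammary tumorigenesis. Each group was 1 library. There were no replicates, so every difference below compares 2 libraries and has no estimate of biological spread. The bulk library had 11306 rows at 1 FPKM or above and the mammosphere library 10495. The control shRNA library had 10553 and the Cbx8 knockdown library 10551.

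Cbx8 (mm9 chromosome 11, 118899749 to 118902227) was at 4.74 FPKM in the control shRNA library and 1.23 FPKM in the knockdown library, 3.84-fold lower as a plain ratio (log2 −1.36 with 1 FPKM added to each value). In the authors' deposited table this had p = 0.0025 and q = 0.385. In the other table Cbx8 was at 3.46 FPKM in bulk cells and 1.48 FPKM in mammospheres, a row the authors did not test. Wdr5 (chromosome 2, 27370666 to 27392055) was at 36.4 FPKM in bulk cells, 43.0 in mammospheres, 73.2 in the control shRNA library and 61.8 in the knockdown library. The tables were made separately, so levels are not compared between them in these results.

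The mammosphere library had higher transcripts of sterol and fatty acid synthesis and of the cell cycle than the bulk library. Its transcripts of immediate early genes, YAP and TEAD targets, luminal and basal lists, extracellular matrix, most inflammatory mediators and antigen presentation were lower. Leukocyte markers (14 of 15 at least 2-fold lower, median −2.91) and fibroblast markers (11 of 12, median −3.33) were lower with them. Most of these marker rows were not tested by the authors, whose status was OK for 2 of 15 and 4 of 12. Here and below, 2-fold counts and log2 changes are on the scale with 1 FPKM added to each value, so a low gene can differ by over 2-fold as a plain ratio without being counted. Of 4045 genes, 151 were at least 2-fold higher and 654 at least 2-fold lower in mammospheres. Higher genes were 18.8% of these. The median ratio of genes expressed in both libraries was −0.21 on the log2 scale. With fold changes centred on that median, 226 were higher and 501 lower, so that higher genes were 31.1%. With upper quartiles set equal, the higher share was 38.2%. In the authors' deposited table, 70 genes were higher and 411 lower at q under 0.05.

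The largest increase was in Lcn2, encoding the secreted iron-siderophore binding protein lipocalin 2, at 27.2 FPKM in bulk cells and 1084 FPKM in mammospheres (log2 fold change 5.27). Mmp3, a secreted metalloproteinase, was at 25.4 and 323 FPKM. Cxcl5, a neutrophil chemokine, was at 6.99 and 78.7 FPKM. Aldh1l2, a mitochondrial folate enzyme, was at 1.28 FPKM in bulk cells and 34.6 in mammospheres. Fabp5, a fatty acid binding protein, was at 11.2 and 112 FPKM, and Nos2, the inducible nitric oxide synthase, at 2.81 and 28.7 FPKM. The largest decreases were in Fosb (821 FPKM in bulk, 1.76 in mammospheres), Ctgf (291 and 0.0405), Cyr61 (1592 and 6.68), Cd74 (164 and 0.0353, in a row shared with a microRNA), Atf3 (753 and 3.87), Col3a1 (128 and 0.0623), Lyz2 (122 and 0.0737), Klf4 (187 and 0.794), Anxa8 (127 and 0.327) and Pdk4 (98.1 and 0.0571). Each of these 16 genes had q under 0.05 in the authors' deposited table.

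**Figure D1:**
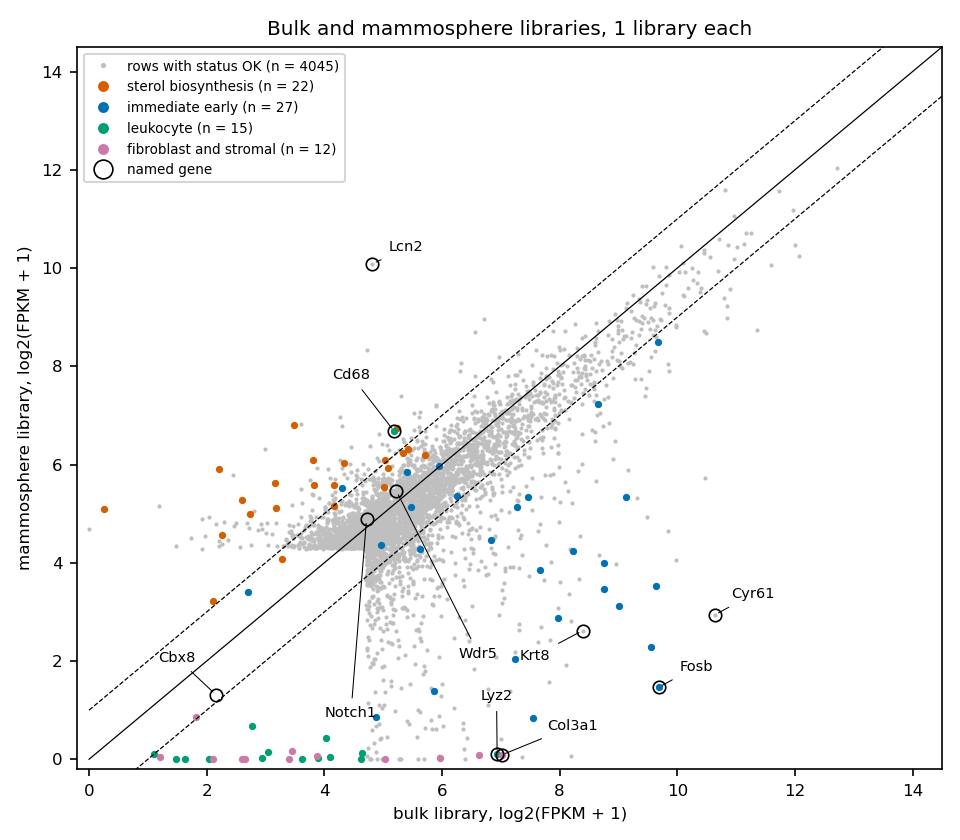
FPKM of the bulk (x axis) and mammosphere (y axis) libraries on the log2(FPKM + 1) scale. Grey points are the 4045 tested rows, coloured points the measured members of 4 lists whatever their status, rings named genes, the solid line equality and dashed lines 2-fold. Lcn2 lies at 27.2 and 1084 FPKM and Cyr61 at 1592 and 6.68 FPKM.

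Of 22 measured sterol biosynthesis genes, 15 were at least 2-fold higher in mammospheres, none was 2-fold lower, and the list median was 1.61, above random lists. The farnesyl diphosphate synthase Fdps was at 10.2 FPKM in bulk cells and 111 in mammospheres, and the cholesterol carrier Stard4 at 5.09 and 37.9. All 12 measured fatty acid synthesis genes had positive log2 changes (median 0.86, above random lists), 5 of them by 2-fold or more. The desaturases Fads2 (4.46 and 54.4 FPKM), Fads1 (12.5 and 50.5) and Scd1 (21.0 and 81.2) were among them.

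Cell cycle genes were also higher. Of 24 G2 and M phase genes, 24 had positive log2 changes (median 0.80), although 5 reached 2-fold. Ccnb1, cyclin B1, was at 32.6 FPKM in bulk cells and 83.0 in mammospheres, and the mitotic kinase Plk1 at 17.2 and 42.1. Of 24 S phase genes, 22 had positive changes (median 0.56) and 1 reached 2-fold, the maintenance methylation factor Uhrf1, at 19.2 and 55.3 FPKM. Both lists lay above random lists. Replication-dependent histone transcripts went the other way. All 14 measured were lower, 9 of them by 2-fold or more (median −1.41, below random lists), including Hist1h2bc at 31.6 and 1.58 FPKM. These histone transcripts mostly lack poly(A) tails, and poly(A) RNA was sequenced here.

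Of 19 genes of the integrated stress response, 8 were at least 2-fold higher and 4 at least 2-fold lower. The median (0.83) lay above random lists although the mean was 0.01. Psph, a serine synthesis enzyme, was at 7.16 FPKM in bulk and 27.0 in mammospheres, whereas Atf3 and the stress regulator Nupr1 (481 and 67.7) were lower. The unfolded protein response list had a median of −0.68, below random lists, with 4 of 14 genes lower by 2-fold or more and 1 higher. Its chaperone Hspa5 was at 2607 FPKM in bulk and 429 in mammospheres, and Herpud1 at 138 and 19.0. Oxidative phosphorylation genes had a median of −0.03, above random lists under the main setting and 3 of 5 alternatives, and none of 26 reached 2-fold. That median was 0.18 after centring and 0.29 with equal upper quartiles.

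Immediate early genes had the lowest median of any list, −3.80, with 20 of 27 genes lower by 2-fold or more and 1 higher. Fos was at 799 FPKM in bulk cells and 10.5 in mammospheres. Of 11 YAP and TEAD targets, 7 were lower by 2-fold or more (median −1.74), including Ankrd1 (109 and 1.15 FPKM) and Amotl2 (62.0 and 1.45). Of 22 extracellular matrix and basement membrane genes, 12 were lower and none higher (median −1.10). Thrombospondin Thbs1 was at 225 and 1.98 FPKM and Fbln2 at 121 and 3.23. The 3 lists lay below random lists.

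The luminal, basal, milk protein and mesenchymal lists were lower. Of 10 luminal genes, 7 were lower by 2-fold or more and none higher (median −1.52), among them the keratins Krt8 (334 FPKM in bulk, 5.14 in mammospheres) and Krt18 (570 and 58.2). Of 8 basal and myoepithelial genes, 6 were lower (median −1.40), with Krt14 at 18.8 and 0.0534 FPKM and smooth muscle actin Acta2 at 29.0 and 6.33. Of 5 milk protein genes, 3 were lower (median −2.47), with Csn2 at 7.92 FPKM in bulk and listed at 0 in mammospheres, whereas Csn3 was at 18.6 and 109.6 FPKM. Of 18 mesenchymal and EMT genes, 9 were lower and 1 higher (median −1.07), with Col1a1 at 97.7 and 0.0589 FPKM and Mmp2 at 60.8 and 0.0516. These 4 lists lay below random lists, although the milk protein call was lost without the FPKM minimum (percentile 2.01). The mammary stem and progenitor list (8 genes, median −0.59) did not. Its members Sox9 (72.3 and 4.55 FPKM) and Klf4 were lower, whereas Itgb3 was at 9.30 and 17.9 FPKM.

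Markers of other cell types moved with the same comparison. Of 15 leukocyte genes, 14 were lower by 2-fold or more in mammospheres (median −2.91), with Tyrobp at 23.7 FPKM in bulk and listed at 0 in mammospheres and Laptm5 at 24.0 and 0.0931. Cd68, a lysosomal protein, was the exception at 35.5 and 101 FPKM, and is named outside the naming rule for that reason. Of 12 fibroblast genes, 11 were lower (median −3.33), and of 4 endothelial genes all 4 were lower (median −1.68), at 6.64 FPKM or less in bulk. All 3 lists lay below random lists, the endothelial one under only 1 of 5 alternative settings. Some of their genes, including Col1a1 and Col1a2, are also in the mesenchymal list. All 15 measured antigen presentation genes were lower (median −1.96), with H2-Ab1 at 47.4 and 0.00726 FPKM. Of 24 inflammatory genes, 18 were lower and 4 higher (median −2.67), with the NF-kappaB inhibitor Tnfaip3 at 109.5 and 1.71 FPKM and Icam1 at 28.4 and 0.11. The 4 higher ones included Lcn2 and Cxcl5, which were among the largest increases given above. Of 24 interferon-stimulated genes, 9 were lower and none higher (median −0.67), with Cxcl10 at 131 and 8.79 FPKM. These 3 lists lay below random lists. The adipocyte list (3 genes, median −0.43) did not, and no erythroid gene was measured.

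The 30 measured Notch pathway genes had a median of −0.62, below random lists, with 8 lower by 2-fold or more and 1 higher. The target gene Hes1 was at 157 FPKM in bulk and 5.76 in mammospheres. The feedback gene Nrarp was at 23.8 and 6.29 FPKM and the ligand Jag1 at 11.5 and 2.94, both untested by the authors. The ligand Jag2 was at 12.9 and 27.1 FPKM, with q = 0.26 in the authors' deposited table. The receptor Notch1 was at 25.3 and 28.5 FPKM. Of 20 PRC1 genes, 2 were at least 2-fold lower with 1 FPKM added, including Rybp (43.5 and 14.01 FPKM). Ring1 and Cbx8 were 2.34-fold lower as plain ratios only, and Cbx2 was at 0.255 FPKM in bulk and 1.13 in mammospheres. The PRC1 median was −0.17, or 0.02 after centring, and did not lie outside random lists. The medians of PRC2 (−0.01), H3K4 methyltransferase complexes (0.08), Wnt genes (−0.33), p53 targets and CDK inhibitors (−0.52), hypoxia and glycolysis (−0.13) and ribosome biogenesis (−0.41) did not either. Ribosomal proteins (median −0.66, 27 of 28 negative) lay at percentile 2.19 with an adjusted share of 0.0612, and were below random lists under 2 of 5 alternatives. The Hox list had fewer than 3 measured members.

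**Figure D2:**
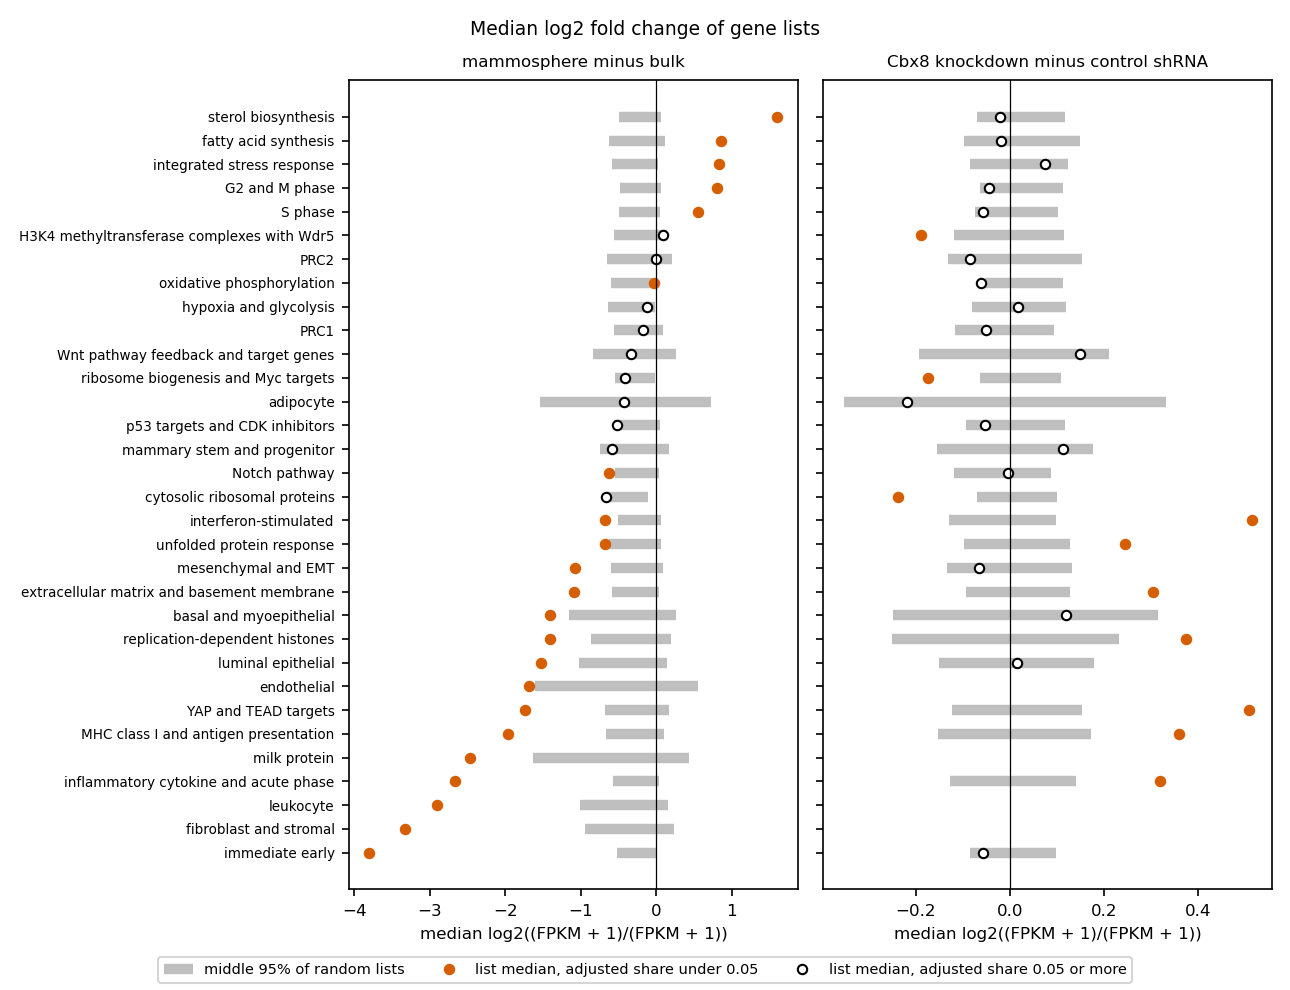
Median log2 fold change of each gene list with 3 or more measured members, for mammosphere minus bulk (left) and Cbx8 knockdown minus control shRNA (right), on axes of different range. Grey bars span the middle 95% of 10000 expression-matched random lists and filled points are lists with an adjusted share under 0.05. Medians run from −3.80 to 1.61 on the left and from −0.24 to 0.51 on the right.

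Beside the lower Cbx8 transcript, the knockdown library differed from its control in few genes by 2-fold or more. Transcripts of YAP and TEAD targets, interferon response and matrix were higher, and those of ribosomal proteins and H3K4 methyltransferase complexes were slightly lower. Of 10685 genes, 32 were at least 2-fold higher and 48 at least 2-fold lower. The table holds no row at 0, so genes silent in a library may be missing from these counts. The median ratio of genes expressed in both libraries was −0.006 on the log2 scale. With upper quartiles set equal, 28 were higher and 54 lower. In the authors' deposited table, 15 genes were higher and 9 lower at q under 0.05. Krt14, a basal keratin, was at 1.09 FPKM in the control and 10.5 in the knockdown library. The prolactin family row Prl2c3 and Prl2c4, near-identical genes listed together, was at 22.4 and 95.04 FPKM. Vgll3, a TEAD cofactor, was at 1.88 and 8.57 FPKM, the natriuretic peptide Nppb at 14.4 and 44.9, Serpinb9b at 42.2 and 113, Serpinb2 at 14.9 and 39.5, Siglecg at 4.61 and 15.3, Elmod1 at 3.01 and 11.0, and Col8a1 at 2.37 and 7.29. Each had q = 0.0325 in the authors' deposited table. S100a7a, at 1.62 and 7.92 FPKM, did not pass there (q = 0.36).

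Among the genes lower in the knockdown library, Mmp3 was at 26.7 FPKM in the control and 9.63 in the knockdown, the carboxypeptidase Cpm at 188 and 74.3, and the imprinted gene Peg10 at 18.4 and 7.34, each with q = 0.0325 in the authors' deposited table. Ptgds (6.49 and 0.359 FPKM), Mgp (14.2 and 3.44), Tnnt3 (5.78 and 1.39), Afap1l1 (13.3 and 4.82) and the RNA component Rmrp (17.6 and 4.99) did not pass there. A row that merges Nupl1 with a microRNA was at 271 and 47.3 FPKM, and its level is uncertain.

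In the Notch pathway, the receptor Notch1 was at 18.1 FPKM in the control and 8.83 in the knockdown library (log2 fold change −0.96), with q = 0.0325 in the authors' deposited table. Jag2 was at 14.6 and 6.85 FPKM and Nrarp at 21.0 and 12.2, with q = 0.23 and 0.95 there. Lfng was at 9.74 and 13.6 FPKM and Hes1 at 18.1 and 13.8. As plain ratios Jag2 and Notch1 were 2.14-fold and 2.05-fold lower, but with 1 FPKM added no member of the 25 measured reached 2-fold, and the list median, −0.003, lay within random lists.

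**Figure D3:**
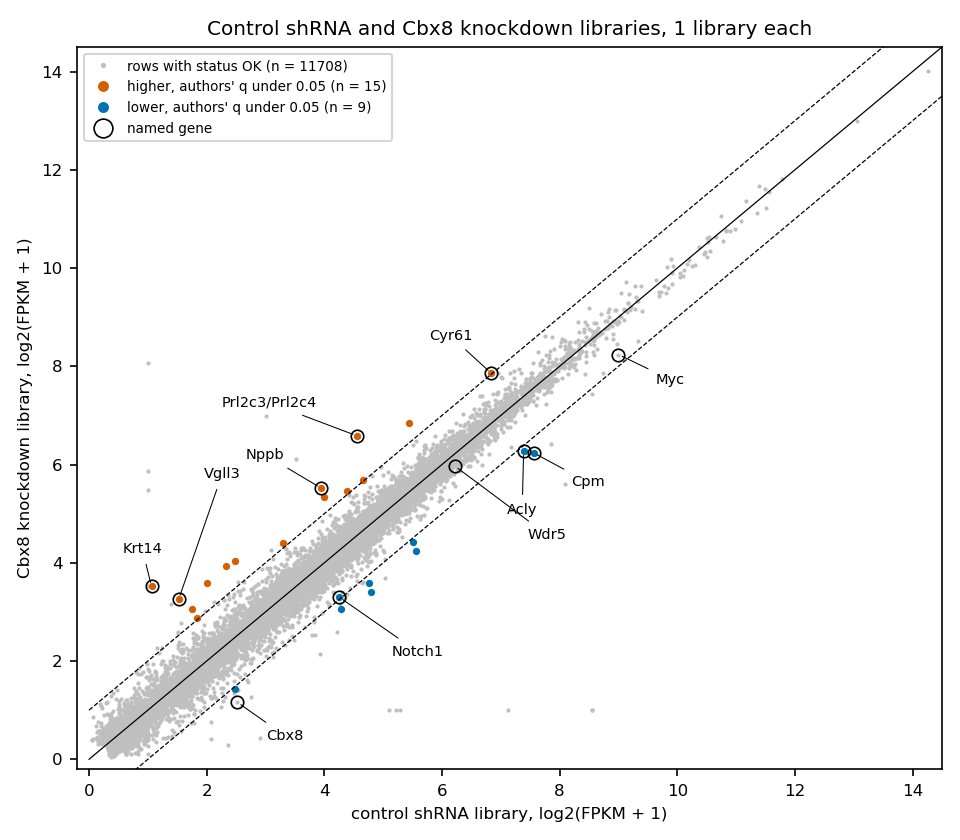
FPKM of the control shRNA (x axis) and Cbx8 knockdown (y axis) libraries on the log2(FPKM + 1) scale. Grey points are the rows of the table, coloured points the 15 higher and 9 lower genes at q under 0.05 in the authors' deposited table, rings named genes and dashed lines 2-fold. Cbx8 lies at 4.74 and 1.23 FPKM, and Notch1 at 18.1 and 8.83.

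Of 10 lists outside random lists, 7 lay above. Interferon-stimulated genes had a median of 0.51, with 19 of 21 positive and Usp18 (4.80 and 11.2 FPKM) past 2-fold. All 11 YAP and TEAD targets had positive changes (median 0.51), including Cyr61 at 113 and 231 FPKM and Ctgf at 27.1 and 53.7. Antigen presentation genes had a median of 0.36 (6 of 9 positive), with H2-K1 at 123 and 177 FPKM. Inflammatory genes had a median of 0.32 (8 of 14 positive), with Csf1 at 50.8 and 81.6. The extracellular matrix median was 0.31 (14 of 17 positive), with the laminin Lamb3 at 1.97 and 5.81. The replication histone median was 0.37 (6 of 7 positive), with Hist1h2bc at 7.52 and 18.1, and its call was lost without the FPKM minimum (percentile 64.0). The unfolded protein response median was 0.24 (13 of 14 positive), with Hspa5 at 529 and 718.

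The 3 lists below random lists were H3K4 methyltransferase complexes with Wdr5 (median −0.19, 16 of 16 negative), ribosome biogenesis and Myc targets (−0.18, 21 of 25 negative) and ribosomal proteins (−0.24, 26 of 28 negative). Of the H3K4 genes, Mll2 was at 6.33 and 4.80 FPKM and Wbp7 at 12.9 and 10.5. Myc itself was at 511 and 301 FPKM. Npm1, a nucleolar protein, was at 477 and 374 FPKM. No member of these 3 lists reached 2-fold. Several ribosomal rows were at very low FPKM in this table, such as Rpl3 at 1.85 and 1.27. Among the 15 ribosomal genes with 100 FPKM or more in the control, all 15 were negative (median −0.23). Sterol, fatty acid and cell cycle list medians lay between −0.06 and −0.02 and within random lists, although Acly, the ATP citrate lyase of fatty acid synthesis, was at 166 and 76.0 FPKM. The medians of PRC1 (−0.05), PRC2 (−0.08), Wnt (0.15), luminal (0.01), basal (0.12), mesenchymal (−0.07), stem and progenitor (0.11), p53 targets (−0.05), hypoxia (0.02), integrated stress response (0.07), immediate early (−0.06) and adipocyte (−0.22) lists also lay within them. The oxidative phosphorylation median (−0.06) lay at percentile 1.66, with an adjusted share of 0.085. The luminal, Wnt and hypoxia lists had means (−0.02, −0.07 and −0.007) of the opposite sign to their medians. Milk, Hox, fibroblast, endothelial and leukocyte lists had fewer than 3 measured members here, and no erythroid gene was listed.

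Genes that differed between mammospheres and bulk cells were followed in the knockdown comparison, each fold change taken within its own table. Of 3952 genes in both, the 141 higher in mammospheres had a median knockdown log2 change of −0.12, below all of the random lists matched on expression, and 98 of them were negative. The 608 lower in mammospheres had a median of 0.11, above all of the random lists, and 394 were positive. Across genes, which are not independent replicates, the 2 fold changes had a Pearson r of −0.23 and a Spearman rho of −0.23. The comparisons share no library. At 2-fold in both, 5 genes were higher in mammospheres and lower in the knockdown, against 0.64 for independent lists, among them Afap1l1, Mmp3, Ndrg2 and Rmrp. Cyr61, Hist1h2bc, Loxl4, Nppb, Serpinb2 and the Prl2c3 row, 6 in all, were lower in mammospheres and higher in the knockdown, against 1.08. No gene was higher in both (0.25 for independent lists) and 4 were lower in both (2.77). Ndrg2 and Loxl4 fall outside the naming rule.

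**Figure D4:**
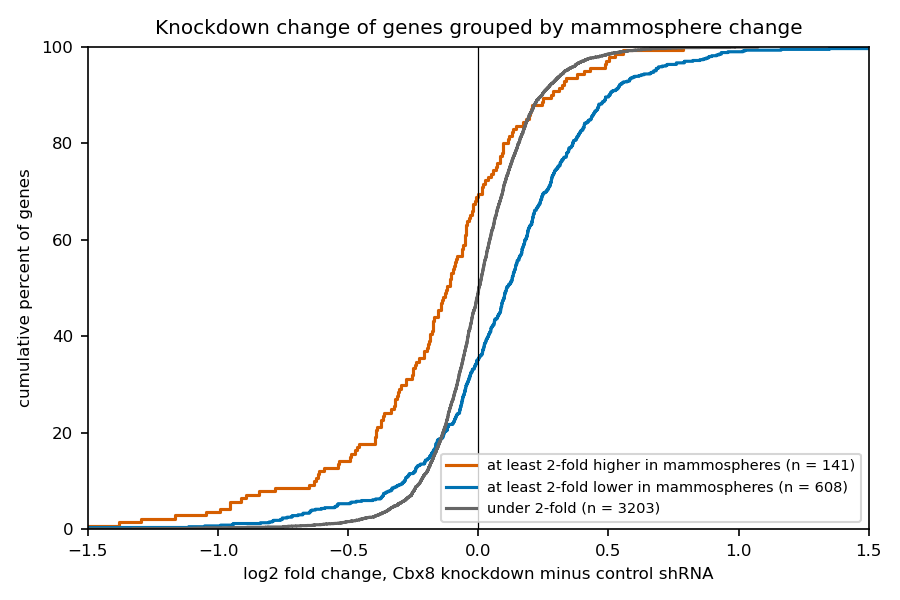
Cumulative percent of genes by log2 fold change of Cbx8 knockdown minus control shRNA, for genes at least 2-fold higher (n = 141), at least 2-fold lower (n = 608) or under 2-fold different in mammospheres against bulk cells. The higher set is shifted left (median −0.12) and the lower set right (median 0.11). A few genes lie beyond the axis limits.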

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

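Alternatives using rows without small RNAs, rows expressed in the control shRNA library, equal upper quartiles for lists, and the gene set comparison without the immediate early, YAP and TEAD, stromal, endothelial and leukocyte lists were chosen only after results were seen. With 1 library per group, no replicate could be left out and no paired analysis was possible. Of 76 alternative counts and set medians, 52 stayed close, a count within 1.5 times its main value and a median within the distance set by the middle 95% of random lists. Some of the 52 could not have differed. Other FPKM minimums left the mammosphere counts as they were, because every tested row lay above them. Without a minimum the knockdown counts could not change, because with 1 FPKM added no gene under 1 FPKM reaches 2-fold. All knockdown rows had status OK, so taking all rows changed nothing there. Of 240 alternative list medians, 215 stayed close and 23 moved in size. Among lists outside random lists 2 changed sign, those of oxidative phosphorylation in mammospheres (0.18 after centring, 0.29 with equal upper quartiles), where a shift of all genes was removed. Medians of PRC1, PRC2 and hypoxia in mammospheres and of Notch, luminal and hypoxia in the knockdown, all within random lists, also changed sign under 1 or both of these settings. Of the 22 mammosphere and 10 knockdown list calls, 19 and 9 held under every alternative.

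Among genes higher in mammospheres, the count became 281 with equal upper quartiles. All rows whatever their status gave 413 higher and 2003 lower genes over 11630 genes. A fold limit of 1.5 gave 354 and 1221, a limit of 4 gave 37 and 263, and the authors' calls 70 and 411. In the knockdown, a pseudocount of 0.1 FPKM gave 88 higher and 114 lower genes and a pseudocount of 5 FPKM gave 14 and 18. Fold limits of 1.5 and 4 gave 224 and 233, and 8 and 10, and the authors' calls 15 and 9. The median knockdown change of genes higher in mammospheres was −0.0807 at a pseudocount of 5 FPKM and −0.0756 at a fold of 1.5. That of genes lower in mammospheres was 0.0853 at a fold of 1.5, 0.15 at a fold of 4 and 0.14 after centring. The cause was not tested. No depth is known, so low FPKM values carry an error that cannot be stated.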

Other observations

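All tests in this part, and the lists of chaperone, glutathione, one-carbon and granzyme genes, were chosen after the results were seen. Serine and one-carbon metabolism genes were higher in mammospheres, with 7 of 15 at least 2-fold higher, 1 lower and a median log2 change of 0.91, above all random lists. Phgdh, Psat1, Psph, Shmt2 and Mthfd2 are also in the integrated stress response list, and Aldh1l2 is among the largest increases. This list thus partly repeats values already reported. Gpt2 was at 3.13 FPKM in bulk cells and 29.4 in mammospheres, Gcat at 3.90 and 27.4, Pck2 at 26.3 and 82.5, and Mthfd2 at 24.4 and 54.6. Of 23 glutathione and NRF2 target genes, 6 were higher and 3 lower (median 0.45). Gstp1 was at 105 and 501 FPKM and Nqo1 at 2.31 and 21.7, whereas Hmox1 was at 74.7 and 28.0 and Osgin1 at 44.6 and 11.1. In the knockdown the medians of these lists were −0.13 (percentile 0.46 of random lists) and 0.16 (percentile 99.7), and no member reached 2-fold with 1 FPKM added. All 10 measured granzyme and cytotoxic cell genes were lower in mammospheres. Gzmf was at 38.3 FPKM and Gzmg at 37.9 in bulk cells, and both were listed at 0 in mammospheres.

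Leukocyte, fibroblast and endothelial transcripts were lower in the mammosphere library: of 31 measured members, 29 (93.5%) were at least 2-fold lower there, and of the 8 members at 20 FPKM or more in bulk cells, 7 were under 1 FPKM in mammospheres. A scaling shift common to all genes was −0.21 at the median gene, too small to give the leukocyte median. That list median stayed at −2.90 after centring, although members near 0 in mammospheres could hardly move. Loss of such cells is argued against for the lower luminal list, whose centred median was −1.40 where a loss of other cells would raise it. Other lower lists, among them the basal, mesenchymal, matrix, inflammatory, interferon and antigen presentation lists, were not checked in this way. Such a loss stays open for them. RNA from such cells in the bulk culture may account for the leukocyte and stromal part, although Cd68 was higher in mammospheres. A difference in state of the tumour cells between growth conditions stays open and untested.

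Immediate early genes were far higher in bulk cells, and their centred median, −3.60, argues against a scaling shift common to all genes. Stress of the bulk cells before lysis was tested with 19 measured heat shock chaperones, 14 of which were at least 2-fold lower in mammospheres (centred median −1.61). Dnajb1 was at 1006 FPKM in bulk cells and 15.5 in mammospheres, and Hspb1 at 1422 and 52.3. Handling and growth condition cannot be told apart here, because each condition has 1 library. Hspa1a and Hspa1b were left out, because the authors' program marked them as holding too many fragments and their 0 in the bulk library is no estimate.

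Some abundant housekeeping transcripts were at very low FPKM in the knockdown table, here set beside the separately made bulk and mammosphere table. Among genes at 100 FPKM or more in bulk cells and mammospheres, 27 of 85 with a pseudogene named after them (31.8%, 95% Wilson interval 22.8 to 42.3) were more than 10 times below the lower of these values in the control shRNA library, against 13 of 361 others (3.60%, 2.12 to 6.06). Without ribosomal protein genes, a split added after those shares were known, the shares were 5 of 41 (12.2%, 5.32 to 25.5) and 10 of 344 (2.91%, 1.59 to 5.27), so the intervals barely part. Genes were sorted by pseudogene symbol alone. The low rows among the others include predicted models such as Gm10136 and Gm6654, and genes whose pseudogenes carry other names count there too. Another scaling of the table is argued against by genes without such a pseudogene, whose median log2 ratio to bulk was 0.11. Lower depth cannot be judged from that ratio, because FPKM is already scaled to library size. Reads shared with pseudogenes may explain part of the low values, and no biological explanation was tested.

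On chromosome 10, in levels from separately made tables, Mdm2 was at 4121 FPKM in bulk cells, 1419 in mammospheres, 3509 in the control and 3576 in the knockdown library, and the nearby Nup107 at 1094, 1093, 3002 and 2976.

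Again across separately made tables, levels in the control shRNA library were set beside those of mammospheres and bulk cells. Of 137 genes higher in mammospheres, 103 (75.2%, 95% Wilson interval 67.3 to 81.7) lay closer to the mammosphere than to the bulk level. Of 591 lower genes, 297 did (50.3%, 46.2 to 54.3). Genes within a library are not independent replicates. These shares cannot tell which culture the control cells stood closer to, because a scaling difference between tables would move them in opposite directions. Summed FPKM was 448025 in the bulk, 322787 in the mammosphere and 466407 in the control shRNA library. Ranks of genes within a library are unchanged by a scaling common to all genes. Over 3770 genes, Spearman rho of the control shRNA library was 0.74 with the mammosphere and 0.61 with the bulk library. Between bulk and mammosphere libraries it was 0.62. By rank, the control library thus lay closer to the mammosphere library. No replicate gives the spread of these values, other differences between the tables could move ranks, and the cause was not tested.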
